A study of Homo sapiens with 8 samples.

How the data were processed

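Human primary aortic smooth muscle cells had been transduced with a lentivirus carrying Flag-tagged progerin or with one carrying Flag alone. Total RNA was sequenced in 8 libraries, 4 per group. Per the labels, the cells were made in 2 independent transductions and each resulting line was sequenced in 2 runs, and the titles number the libraries within a group without saying which line or run a number stands for. The p-values below therefore measure only the spread between libraries, part of which may be technical.

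Per the submitters' processing notes, bcl2fastq, STAR, Subread and featureCounts were used. The genome build, the annotation, the strand setting and the filter on low genes are not given in the sources used here, so no coordinates are printed and overlapping or antisense genes were not separated. Genes are named by the Ensembl ID and symbol that the table pairs, and all 13637 IDs had a symbol.

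The values deposited by the authors are log2 CPM in 8 library columns, beside the authors' own comparison of the groups with its log2 fold change, p-value and adjusted p-value, and its linear fold. Per the file headers, the moderated statistic and the log-odds score come from the same model of the authors, and neither score was used except to correlate the statistic with the one computed here. The table has 13668 entries, 31 of which repeat a gene ID, and 13637 genes were analysed here. Low values form no steps of whole reads: in the library control A1, 215 genes lay under 1 CPM with 213 distinct values. The depth of the libraries is therefore unknown, no counting interval can be given, and fold changes of genes near the floor depend on the offset the authors added before taking logs. The listed genes summed to between 872338 and 1055847 CPM per library, and 1 library thus exceeds the total that plain CPM allows, so the values carry a further scaling that is not given in the sources used here.

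The column names give the group and carry no number of the titles. Within each group 2 columns have names without a number, called pair A here, and 2 have names ending in 1 or 2, called pair B. The names do not say that a pair is a line or a run, or that pair A of one group was handled with pair A of the other. Column pairs were used to compare results within and between them.

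Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend, on the deposited log2 values and with no covariate. P-values were adjusted by the Benjamini-Hochberg method over 13637 genes, with a threshold of 0.05. No further filter or pseudocount was applied. The planned test for log2 values was used as written. A term for the column pair, each pair alone, and the interaction of group and pair were fitted in the same way. Of 34 gene lists, 32 had at least 5 measured members and were tested with camera (preset correlation 0.01), which compares a list with all other genes, with adjustment over the 32 lists. Camera was repeated with a correlation estimated for each list. Fry tests whether the genes of a list move on balance one way and does not compare them with other genes.

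The lists, the rule for naming genes, the main test and the first set of alternatives were fixed before the data were examined. The rule names LMNA, ACTA2, MYH11, CNN1 and TAGLN, the 10 largest rises and 10 largest falls among called genes with a mean of at least 5 CPM and groups that do not overlap, and up to 4 members of each list with the lowest adjusted p and a mean of at least 1 CPM. Not all of these are printed, and some are not reported here. CDKN1A, MKI67, CDC20, FGF7, CSF1 and FOXF1, and the gene families among the other observations, were chosen after their values were seen. XIST and Y-linked genes were left out of everything printed.

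The fit was tested on simulated data with 4 libraries per group and 13637 genes. It recovered 46.6% of genes changed about 1.5-fold, 71.9% of genes changed by 1 on the log2 scale and 94.1% of genes changed by 2, with 4.82% false calls on average. The simulated libraries were independent, with no lines, runs or column pairs. The false share in the real libraries may therefore differ. Camera called 50 of 50 shifted lists and 2 of 250 unshifted lists, in simulated genes that varied independently of each other. Alternatives were quantile normalization, a mean of at least 5 CPM, no trend, pseudocounts of 0.1 and 5 CPM, libraries averaged in pairs, each library left out, and the set tests above. Added after the data were seen were the column-pair fits, the column-ending fit, array weights and median-ratio centring. Figures were drawn with matplotlib 3.10.9.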

Results

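Transcript levels of 13637 genes were measured in 4 libraries of human primary aortic smooth muscle cells expressing Flag-progerin, the truncated form of lamin A made in Hutchinson-Gilford progeria, and in 4 libraries of cells carrying Flag alone. Values are log2 CPM as deposited, errors of log2 fold changes are SE with n = 4 libraries per group, and sequencing depth is unknown. The first principal component held 59.1% of the variance and separated the groups, with all 4 progerin libraries on one side. The libraries progerin A1 and progerin A2 correlated with each other at a Spearman coefficient of 0.981 across genes, against 0.994 to 0.996 for the other 3 pairs of columns, and limma's array weights were lowest for progerin A2 (0.272) and progerin A1 (0.567).

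The series asked what progerin expression does to vascular smooth muscle cells. LMNA (ENSG00000160789), the gene from which the transgene derives, stood at 10.29 ± 0.08 log2 CPM in control libraries and 10.86 ± 0.26 in progerin libraries (SD, n = 4), and each progerin library lay above each control library. The rise was 0.58 ± 0.13 (adjusted p = 0.0230), and the gene-level values do not separate transgene from endogenous transcripts. Among the genes that fell with progerin were 11 of 22 contractile genes, 15 of 38 matrix proteins other than collagens and 5 of 9 endothelial markers, and 9 of 16 NRF2 antioxidant genes rose. As lists, these had adjusted p-values of 0.346, 0.396, 0.346 and 0.405 with an estimated correlation. With the 8 libraries taken as the unit, 2375 of 13637 genes (17.4%) changed, 1018 higher and 1357 lower. A change of at least 2-fold was found in 636 of them, 98 higher and 538 lower. After quantile normalization the calls were split into 1191 higher and 1224 lower, and those of at least 2-fold into 174 and 433. With the deposited scaling and only genes with a mean of at least 5 CPM, the calls were 972 higher and 991 lower. Those of at least 2-fold were then 65 and 262. The groups did not overlap in 2250 of the 2375 called genes and in 3548 of all genes. Chance gives 2.86% only if the 8 libraries are independent, which 2 lines per group in 2 runs each do not provide. Among called genes the lack of overlap also follows in part from the call itself. With a term for the column pair 1979 genes were called, of which 1943 were also called without it in the same direction. Matching the columns of the groups by the endings of their names called 411. The labels give 2 independently made lines per group, and averaging the libraries within each column pair, which leaves 2 values per group, left 0 genes called by limma, with 2652 at an unadjusted p under 0.05. The names do not tie a pair to a line, and the other ways of averaging libraries in pairs called from 257 to 3946 genes. Leaving out a single library lowered the count of 2375 by more than 1.5 times in 4 cases: to 525 without control B1, 533 without control B2, 1314 without progerin B1 and 1574 without progerin B2. The count of 636 genes changed at least 2-fold fell to 265 without control B1 and 258 without control B2. The authors' deposited table lists 4678 genes under an adjusted p of 0.05, 2270 higher and 2408 lower, and 2368 of the 2375 genes called here are among them in the same direction. Both rest on the same 8 libraries, so the overlap is no independent test. The authors' moderated statistic correlated across genes at 0.958 with the one computed here. With array weights and the column-pair term that correlation was 0.986, and 4410 genes were called.

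Among genes with a mean of at least 5 CPM and groups that did not overlap, the largest rises were those of FENDRR (ENSG00000268388), a long noncoding RNA (3.54 ± 0.53, adjusted p = 0.00863), SLC6A15, an amino acid transporter (3.21 ± 0.45), NPTX1, a neuronal pentraxin (2.73 ± 0.49), GREM1, a secreted BMP antagonist (2.65 ± 0.42), and ZNF804A (2.56 ± 0.49). TRHDE, SECTM1, TENM3, MIR503HG and TSHZ1 followed, with log2 fold changes of 2.40, 2.31, 2.29, 1.89 and 1.87. GREM1 was the most abundant of these 10, at 10.12 ± 0.61 log2 CPM in progerin libraries (SD, n = 4). Under the same limits the largest fall was that of ACAN (ENSG00000157766), the cartilage proteoglycan aggrecan, from 4.94 ± 0.15 to -2.38 ± 1.67 log2 CPM (SD, n = 4; log2 fold change -7.32 ± 0.70, adjusted p = 0.00250). ANOS1 (-6.64 ± 1.68), the succinate receptor SUCNR1 (-5.63 ± 0.81), ADAMTS17 (-4.92 ± 1.46) and the transcription factor FOXS1 (-4.73 ± 0.64) came next. NDUFA4L2, the water channel AQP1, the integrin subunit ITGA8, GDF6 and SORBS2 had log2 fold changes of -4.46, -4.17, -4.00, -3.79 and -3.79. The sizes of the falls of ACAN, ANOS1, ADAMTS17, FOXS1 and SORBS2 depend on the authors' offset, since the means of their log2 CPM in progerin libraries lay below 0. The same holds for the rise of FENDRR, whose mean in control libraries was -0.04. Among genes named below it holds for MMP3 and HEY1 (control mean below 0) and for COL4A3, BST2 and PRELP (progerin mean below 0).

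The 4 contractile markers fixed in advance were lower with progerin. ACTA2 (ENSG00000107796), smooth muscle actin, fell from 7.19 ± 0.50 to 5.89 ± 0.21 log2 CPM (SD, n = 4), a log2 fold change of -1.30 ± 0.23 (adjusted p = 0.0116). TAGLN, encoding transgelin, fell by 0.76 ± 0.17 (adjusted p = 0.0212), CNN1, encoding calponin, by 0.93 ± 0.25 (0.0374) and MYH11, smooth muscle myosin heavy chain, by 0.73 ± 0.21 (0.0478). The CNN1 values of the groups overlapped, and MYH11 was low, at a mean of 1.97 CPM in control and 1.20 in progerin libraries. MYOCD, a coactivator of contractile gene transcription, fell by 2.87 ± 0.34 and PDLIM7 by 0.40 ± 0.08. Of 22 contractile genes measured, 11 fell, none rose and 11 did not pass the test, and 11 were lower adjusted over the list alone (camera adjusted p = 0.000616; 0.346 with an estimated correlation). In column pairs A and B the median log2 fold change of the list was -0.44 and -0.47, but 7 of the 22 genes differed between the pairs. With the spread shared over the 8 libraries 7 fell and 0 rose in pair A and 11 fell and 3 rose in pair B. The log2 fold changes in pairs A and B were -0.94 and -1.67 for ACTA2, -0.45 and -1.07 for TAGLN. They were -0.43 and -1.43 for CNN1 and -0.35 and -1.11 for MYH11. Of these 4 markers only ACTA2 passed limma's test in pair A (adjusted p = 0.0327), and all 4 passed in pair B. None of the 4 differed between the pairs by the interaction test (lowest adjusted p = 0.122, CNN1). With the column-pair term the adjusted p of CNN1 was 0.0516 and that of MYH11 0.0720. Of 23 targets of the actin-regulated factors SRF and MRTF, 7 fell and 0 rose (8 lower adjusted over the list alone), among them FHL1 (-1.91 ± 0.28) and the nonmuscle myosin MYH9 (-0.61 ± 0.13), with a camera adjusted p of 0.00465, which was 0.346 with an estimated correlation.

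**Figure D1:**
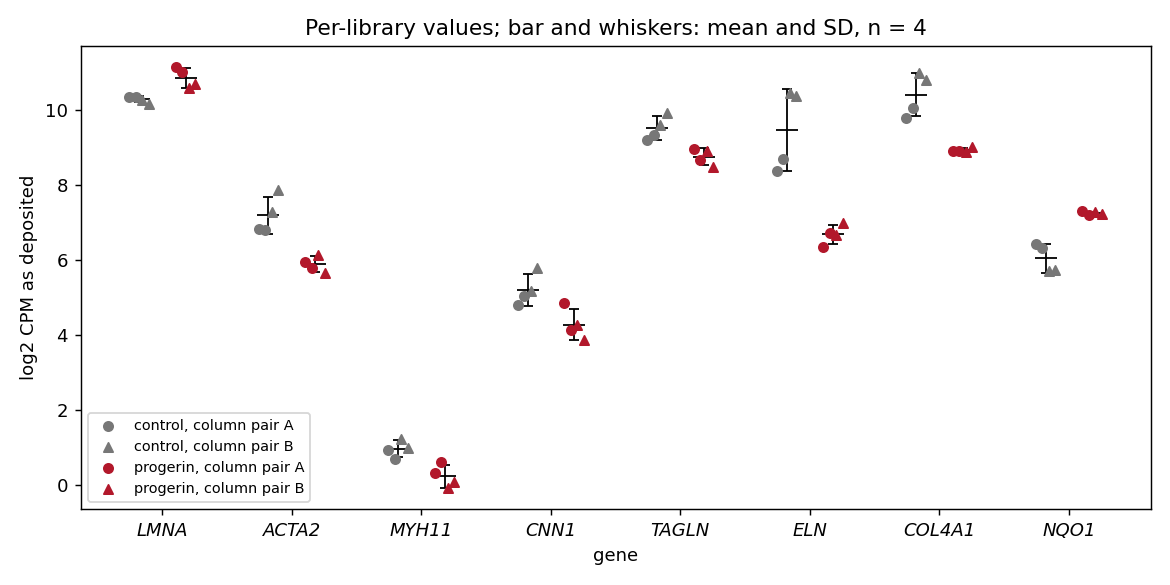
Log2 CPM (vertical axis) of 8 named genes (horizontal axis) in each of the 8 libraries, grey for control and red for progerin, with circles for column pair A and triangles for pair B; the horizontal bar is the mean and the whiskers the SD of 4 libraries. ACTA2 lies at 7.19 in control and 5.89 in progerin libraries on average, and LMNA at 10.29 and 10.86.

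Genes of the synthetic smooth muscle state, which dividing and matrix-producing cells express, did not rise as a group. Of 18 measured, 7 fell and 0 rose (10 lower adjusted over the list alone; camera adjusted p = 0.00482, and 0.346 with an estimated correlation). These included ELN, encoding elastin (-2.78 ± 0.47), MGP, an inhibitor of calcification (-2.05 ± 0.28), and the cyclin CCND1 (-1.12 ± 0.25). Among other matrix proteins 15 of 38 fell and 0 rose (20 lower and 4 higher adjusted over the list alone; camera adjusted p = 0.000687, and 0.396 with an estimated correlation), PRELP by 3.01 ± 0.38 and the cartilage protein COMP by 1.45 ± 0.24. Of 24 collagen genes 6 fell and 0 rose (7 lower and 1 higher adjusted over the list alone), and the list was not called (adjusted p = 0.250). The basement membrane chains COL4A1 (-1.47 ± 0.24) and COL4A2 (-1.39 ± 0.26), COL18A1 (-0.67 ± 0.16) and COL4A3 (-3.41 ± 0.81) were among the 6. The collagen medians had opposite signs in pairs A and B (-0.34 and 0.26). Between the pairs, 10 of 24 collagens and 17 of 38 other matrix proteins differed. In pair B 5 collagens were higher and 8 lower, against 0 and 5 in pair A. Other matrix proteins were higher in 9 cases and lower in 17 in pair B, against 0 and 16 in pair A. Of 24 matrix proteases and inhibitors, 3 rose and 1 fell, with the same counts adjusted over the list alone (list adjusted p = 0.848): the stromelysin MMP3 (3.71 ± 0.81), the aggrecanase ADAMTS5 (1.87 ± 0.35) and ADAMTS12 (0.43 ± 0.10) rose. Osteochondrogenic genes fell in 4 of 16 cases and rose in 0 (5 lower and 2 higher adjusted over the list alone; list adjusted p = 0.0693), with SOX9 at -0.83 ± 0.20. With the column-pair term the camera adjusted p of this list was 0.0381, and 0.251 with an estimated correlation as well. Of 20 TGF-beta targets, 5 fell and 1 rose (6 and 4 adjusted over the list alone; list adjusted p = 0.237), with PMEPA1 at -0.99 ± 0.15, LTBP3 at -0.85 ± 0.16 and ID1, a BMP target, at 0.62 ± 0.12. Of 11 Notch pathway genes 2 fell and 1 rose (3 and 1 adjusted over the list alone; list adjusted p = 0.231): the ligand JAG1 (-0.61 ± 0.10), the receptor NOTCH3 (-0.68 ± 0.17) and HEY1 (0.90 ± 0.26), whose adjusted p was 0.0630 with the column-pair term. HEY2 (-2.26 ± 0.69) had an adjusted p of 0.0543, and 0.0467 with that term, with which 0 Notch pathway genes rose and 3 fell.

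Of 16 NRF2 genes, 9 rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.000790; 0.405 with an estimated correlation). They included NQO1 (1.21 ± 0.17), the cystine transporter SLC7A11 (1.49 ± 0.28), TXNRD1 (0.92 ± 0.18) and TXN (0.32 ± 0.07). Of 21 hypoxia and glycolysis genes 6 fell and 0 rose (7 lower adjusted over the list alone; camera adjusted p = 0.00151, and 0.435 with an estimated correlation), with ENO2 at -1.14 ± 0.18 and ALDOC at -1.04 ± 0.16. Of 27 p53 targets 8 rose and 1 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.0125, and 0.396 with an estimated correlation). FDXR (0.53 ± 0.10), the repair factor XPC (0.33 ± 0.08) and the phosphatase PPM1D (0.56 ± 0.13) rose and PLK3 fell (-0.37 ± 0.09). Of 22 cholesterol synthesis genes none passed the limma test, over all genes or adjusted over the list alone (list adjusted p = 0.238). At an unadjusted p under 0.05, 3 of them were higher and 3 lower. Of 22 unfolded protein response genes 1 fell, ATF3 (-1.36 ± 0.24), which was also the 1 found adjusted over the list alone (list adjusted p = 0.302). With the spread shared over the 8 libraries, 9 cholesterol synthesis genes were higher and 1 lower in pair B, against 0 and 1 in pair A, and 7 differed between the pairs. For the unfolded protein response these counts were 7 and 2, 0 and 1, and 4.

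None of the lists of secretory, inflammatory and senescence genes was called with camera, and fry called 1 of them, nucleic acid sensing (adjusted p = 0.0135, higher). Of 43 secretory genes linked to senescence, 1 rose and 6 fell, with the same counts adjusted over the list alone (list adjusted p = 0.977). The 6 included the growth factor binding proteins IGFBP2 (-2.79 ± 0.56), IGFBP3 (-1.84 ± 0.26) and IGFBP7 (-1.17 ± 0.20) and the chemokine CCL2 (-1.47 ± 0.34). The balance turned round in pair B, where with the spread shared over the 8 libraries 15 were higher and 8 lower, against 0 and 5 in pair A. Interferon-stimulated genes were higher in 11 cases and lower in 1 in pair B, against 0 and 3 in pair A. Of 34 interferon-stimulated genes 4 rose and 2 fell, with the same counts adjusted over the list alone (list adjusted p = 0.237): PSMB8 rose by 0.64 ± 0.12 and IFIT5 by 0.38 ± 0.10 (adjusted p = 0.0506 with the column-pair term), and BST2, encoding tetherin, fell by 3.31 ± 0.33. Of 14 nucleic acid sensing genes 2 rose, 3 adjusted over the list alone (list adjusted p = 0.119): the DNA sensor CGAS (0.84 ± 0.17) and ADAR (0.21 ± 0.06, adjusted p = 0.0555 with the column-pair term). NF-kappaB targets fell in 3 of 23 cases and rose in 1, with the same counts adjusted over the list alone (list adjusted p = 0.528), with TRAF1 at -1.67 ± 0.21, TNFAIP3 at -0.90 ± 0.15 and NFKB1 at 0.40 ± 0.09. Of 14 antigen presentation genes 2 rose and 1 fell, with the same counts adjusted over the list alone (list adjusted p = 0.302): B2M rose (0.34 ± 0.10, adjusted p = 0.0554 with the column-pair term) and HLA-DMA fell (-0.89 ± 0.21). Of 16 senescence and cell cycle inhibitor genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone; list adjusted p = 0.626), and the inhibitors CDKN2A (-0.59 ± 0.12) and CDKN2B (-0.76 ± 0.12) were the 2 that fell. The inhibitor CDKN1A (0.32 ± 0.09), the lysosomal galactosidase gene GLB1 (0.32 ± 0.09) and HMGB1 (0.56 ± 0.12) were the 3 that rose, with adjusted p-values of 0.0511, 0.0617 and 0.00945 with the column-pair term. Nuclear lamina and envelope genes rose in 3 of 23 cases and fell in 3 (5 and 4 adjusted over the list alone; list adjusted p = 0.302), with LBR at 0.69 ± 0.18 and SUN1 at -0.44 ± 0.08.

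Few genes of replication, repair and mitosis changed over the 8 libraries. Of 47 replication genes 1 rose, POLD3 (0.59 ± 0.14), and 0 adjusted over the list alone (list adjusted p = 0.231). Of 48 mitosis genes 1 rose, CDC25B (0.81 ± 0.12), also 1 adjusted over the list alone (list adjusted p = 0.323). Of 50 repair and fork protection genes 5 rose and 0 fell (1 higher adjusted over the list alone; list adjusted p = 0.0693), with NBN at 0.42 ± 0.08 and RAD51D at 0.47 ± 0.12. The camera adjusted p of the repair list was 0.0484 with the column-pair term, and 0.863 with an estimated correlation as well. None of 6 histone genes or 43 ribosomal protein genes passed the limma test, over all genes or adjusted over the list alone, and 0 and 1 had an unadjusted p under 0.05 (list adjusted p = 0.724 and 0.924). Of 13 mitochondrially encoded genes 1 fell, MT-ND6 (-0.31 ± 0.08), with 0 adjusted over the list alone (list adjusted p = 0.231).

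Of 44 markers of other cell types in 7 lists, 15 fell, 3 rose and 26 did not pass the test. Of 9 endothelial markers 5 fell and 0 rose (8 lower adjusted over the list alone; camera adjusted p = 0.000535, and 0.346 with an estimated correlation), with PECAM1 at -1.00 ± 0.16, EMCN at -1.41 ± 0.25 and KDR, a VEGF receptor, at -1.53 ± 0.32. Pericyte markers, several of which smooth muscle also expresses, fell in 4 of 8 cases and rose in 1 (5 and 2 adjusted over the list alone; list adjusted p = 0.0693), with RGS5 at -3.11 ± 0.47, CSPG4 at -1.34 ± 0.20 and ABCC9 at 1.01 ± 0.19. The camera adjusted p of the pericyte list was 0.0326 with the column-pair term, and 0.335 with an estimated correlation as well. Of 5 neural markers 2 fell (4 adjusted over the list alone; camera adjusted p = 0.00818, and 0.346 with an estimated correlation). These were NEFM (-1.95 ± 0.40) and ENO2 (-1.14 ± 0.18), which is also in the hypoxia and glycolysis list. Of 6 epithelial markers 2 fell, KRT8 (-1.05 ± 0.17) and KRT7 (-3.18 ± 0.84), and 3 adjusted over the list alone (list adjusted p = 0.141). Of 13 fibroblast markers 1 rose and 2 fell (1 and 3 adjusted over the list alone; list adjusted p = 0.805), with PI16 at -2.02 ± 0.38. A single macrophage marker was measured, CD14 (-2.34 ± 0.78, adjusted p = 0.0685, and lower adjusted over the list alone), and of 2 adipocyte markers PPARG rose (1.17 ± 0.19), also adjusted over the list alone. Those 2 lists were too small to test. In all, 9 of 32 lists were called with the preset correlation, 2 higher and 7 lower, and 0 with an estimated correlation, where 2 lists had an unadjusted p under 0.05. Some called lists share members, such as TAGLN, ELN and ENO2, and are not separate results. Of the 35 divisions of the 8 libraries into 4 and 4, 27 called at least 9 lists, and the highest called 17.

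The column pairs differed in what progerin libraries showed. Mitosis genes were higher with progerin in pair A, where the median log2 fold change was 0.86, and lower in pair B, where it was -1.45. The proliferation marker MKI67 had log2 fold changes of 0.98 and -2.35 in pairs A and B (interaction adjusted p = 0.00107), and CDC20, an activator of mitotic exit, 1.24 and -1.71 (0.00118). With the spread shared over all 8 libraries, 21 of 48 mitosis genes rose in pair A and 44 fell in pair B, and 42 differed between the pairs. With the pairing crossed, which the column names do not rule out, 6 of 48 differed, with medians of 0.28 for progerin A against control B and -0.92 for progerin B against control A. The list differed between the pairs at a camera adjusted p of 8.93e-31, and 0.472 with an estimated correlation. Replication genes had medians of 0.60 and -0.40 in pairs A and B and repair genes 0.47 and -0.22, and 20 of 47 and 17 of 50 of them differed between the pairs, with 16 of each list lower in pair B and 0 in pair A. Secretory genes had medians of -0.30 and 0.59, with 16 of 43 differing, among them the growth factor FGF7 (-0.76 and 2.06) and the cytokine CSF1 (-0.22 and 1.49). Fibroblast markers had medians of -0.27 and 1.08, with 7 higher and 2 lower in pair B against 1 and 4 in pair A, and NRF2 genes 0.19 and 0.72.

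Across all genes 1972 changed differently in the pairs by the interaction test in limma, 931 more positive in pair B and 1041 more negative. Of these, 108 were higher in one pair and lower in the other with both changes past the threshold. Each pair alone called 106 genes (A) and 5642 genes (B), and 971 and 4685 with the spread shared over the 8 libraries. Fold changes of the pairs correlated at r = 0.357 across genes, which are not independent replicates. Progerin libraries of pair B differed from those of pair A in 1468 genes and control libraries in 108. The interaction count fell to 591 without control A1, 705 without control A2, 746 without control B1, 803 without control B2, 1238 without progerin B1 and 1067 without progerin B2, and was 3956 without progerin A1.

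**Figure D2:**
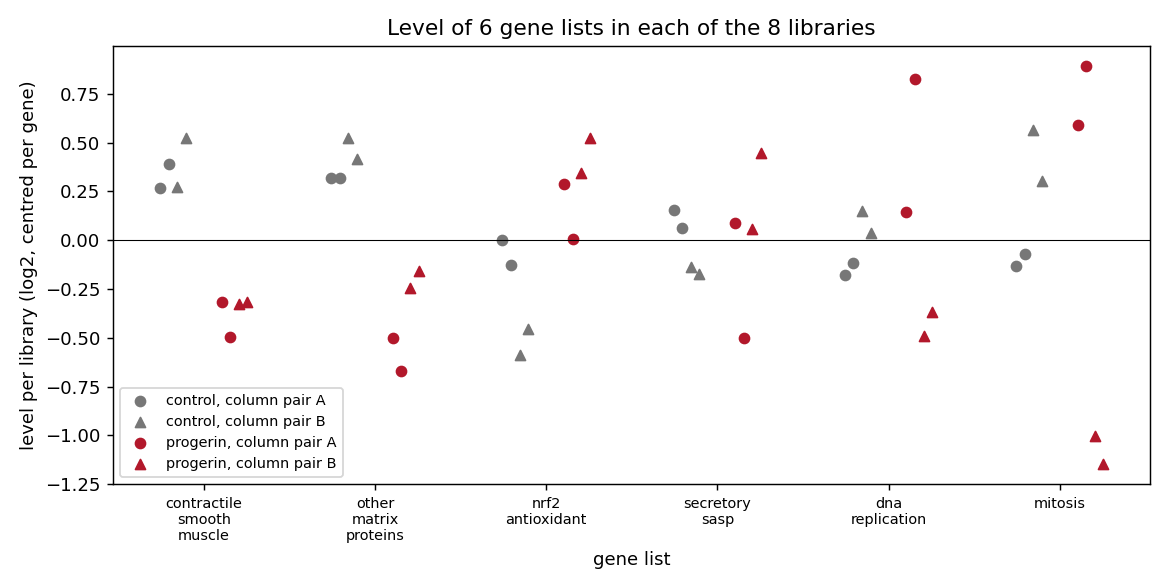
Level of 6 gene lists (horizontal axis) in each of the 8 libraries, as the mean over members of log2 CPM after subtracting each gene's mean over the libraries (vertical axis, log2); grey is control, red is progerin, circles are column pair A and triangles pair B. Mitosis genes lie at 0.59 and 0.89 in the progerin libraries of pair A and at -1.00 and -1.15 in those of pair B.

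**Figure D3:**
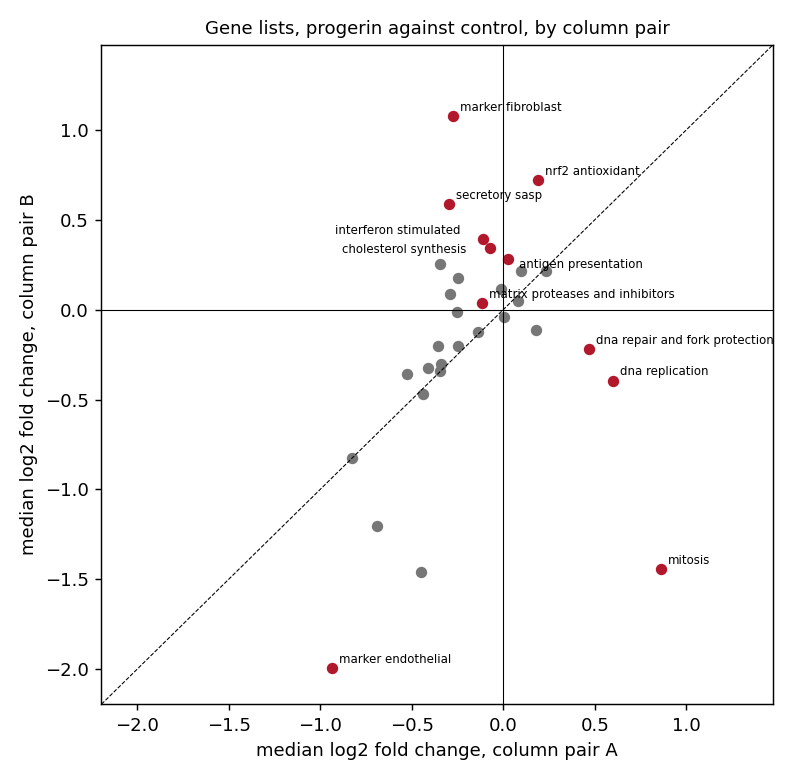
Median log2 fold change of progerin against control for the 32 tested gene lists in column pair A (horizontal axis) and pair B (vertical axis), each from 2 libraries per group; red and named are the 11 lists that differed between the pairs with camera's preset correlation, and the dashed line marks equal changes. The mitosis list lies at 0.86 in pair A and -1.45 in pair B.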

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

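The tests of the column pairs, of label swaps, of crossed pairing, of scaling, of mitosis genes with a library left out and of the wider spread in pair A were chosen after the results they measure had been seen, and the pairs themselves were defined from the column names after the data were examined. The tests of other divisions of the libraries and the count in each pair without progerin A2 were written down before those results were seen.

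All 35 divisions of the 8 libraries into 4 and 4 were fitted with limma. The real division called 2375 genes and the highest of the others 0, so 1 of 35 gave as many. This excludes chance division only if the 8 libraries are independent. With 2 lines per group sequenced in 2 runs each it does not. Averaging within column pairs, which the names do not tie to lines, left 0 genes. The others reached up to 2849 genes at an unadjusted p under 0.05, against 4833. For changes of at least 2-fold the values were 636 and 0, again 1 of 35. This is no separate result, since a division that calls 0 genes has none of at least 2-fold. Every other division also mixes the groups, so the difference between groups widens the spread on each side and makes calls unlikely. For gene lists 27 of 35 divisions called at least the 9 of the real one and the highest other called 17, so chance division cannot be excluded for the number of called lists. Camera with its preset correlation thus called lists in divisions that called 0 genes.

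Mitosis genes were higher with progerin in column pair A and lower in pair B, with medians of 0.86 and -1.45, and 42 of 48 genes differed between the pairs. A swap of progerin and control libraries within 1 pair would turn the fold changes of the other genes around as well, but outside the mitosis, replication and repair lists these correlated at 0.378 across genes. With the pairs crossed (progerin A with control B), 6 of 48 genes differed, and the library means of the list differed by -1.28 against -2.35. Crossing the pairs thus left -1.28 of the difference in these library means. The median mitosis gene differed by -1.73 between the progerin pairs (B minus A) and by 0.55 between the control pairs. The spread behind both fits comes from the 2 libraries inside each column pair, which may be runs of 1 line. Whether what remains with the pairs crossed exceeds the spread between lines therefore stays open. Without progerin A2 42 of 48 genes differed, with each of the 8 libraries left out in turn 34 to 46, and after quantile normalization 44, which argues against any 1 of these libraries or the scaling as the whole cause. A difference between the independently made lines or between runs stays open, since the names do not tie columns to either, and no biological explanation was tested.

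Pair B called more genes than pair A. With 1 spread shared over the 8 libraries the count in B was still 4.82 times that in A, so wider spread in pair A, where the median SD between the 2 progerin libraries was 0.157 against 0.102 in pair B (0.0682 and 0.0911 for the control libraries), does not account for it alone. Without progerin A2 the ratio was 4.22. The median absolute fold change was 0.20 in A and 0.31 in B. LMNA rose by 0.73 in A and 0.42 in B, which did not differ by the interaction test in limma (adjusted p = 0.233). What distinguishes the pairs stays open, and no biological explanation was tested.

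By the interaction test, whose error comes from libraries that may be runs of 1 line, 1972 of 13637 genes (14.5%) changed differently in the pairs. Among the named genes that did, MKI67, CDC20, FGF7 and CSF1 had been picked because they differed. The difference of log2 fold changes, pair B minus pair A, was positive for GREM1 (1.94), ZNF804A (1.44), SECTM1 (2.06), TSHZ1 (1.06), ADAMTS5 (1.63), NQO1 (0.67), SLC7A11 (1.50), TXNRD1 (0.86), FGF7 (2.82) and CSF1 (1.71). It was negative for ACAN (-2.99), ANOS1 (-7.29), ADAMTS17 (-6.95), GDF6 (-3.57), SORBS2 (-4.15), ELN (-1.60), CCND1 (-1.27), COL4A1 (-0.92), COL4A2 (-1.14), COL4A3 (-3.77), IGFBP2 (-2.98), IGFBP3 (-0.81), EMCN (-1.32), KRT7 (-3.85), RGS5 (-1.90), CSPG4 (-0.70), CD14 (-3.63), MKI67 (-3.33) and CDC20 (-2.95). The sizes for ACAN, ANOS1, ADAMTS17, SORBS2 and COL4A3 depend on the authors' offset, since their mean log2 CPM in progerin libraries lay below 0. Pseudocounts were not tried for the interaction. Of 32 lists, 11 differed between the pairs with the preset correlation and 0 with an estimated one, where the lowest adjusted p was 0.472. Their median differences were 0.42 for matrix proteases, 0.83 for secretory genes, 0.53 for interferon-stimulated genes, 0.55 for antigen presentation, 0.32 for cholesterol synthesis, 0.56 for NRF2 genes, 1.94 for fibroblast markers, -0.94 for replication, -2.27 for mitosis, -0.61 for repair and -1.32 for endothelial markers.

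In 7 of 202 groups of 4 libraries, 1 library stood apart from the other 3 for a named gene, and chance gives about 1 in 20. The measure was the gap relative to the range of the 4 libraries, so a flagged gap can be small. For CSPG4 the other 3 progerin libraries lay at 5.93 to 5.94. The flagged values in log2 CPM were 9.21 for GREM1 in progerin A2, 5.43 for TRHDE in progerin A1, 6.77 for ADAMTS12 in control B2, 5.25 for NFKB1 in control A2, 2.46 for POLD3 in control B2, and in progerin A2 5.82 for CSPG4 and 2.24 for NEFM.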

How the results depend on the processing

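The alternatives using column pairs, column endings, array weights and median-ratio centring, and all those for the interaction, were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate numbers of the titles. The column-ending term matches columns by name only. Endings shared by the groups deviated in opposite directions, with correlations from -0.44 to -0.29, and the crossed column-pair term called 4162 genes. The comparison with no filter was not run because the main fit applies none, and count tests were not run because no counts could be recovered. Depth is unknown.

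The count of 2375 genes stayed within 1.5 times under quantile normalization (2415), a mean of at least 5 CPM (1963), no trend (1954), pseudocounts of 0.1 and 5 CPM (2424 and 2536), the column-pair term (1979), array weights (2682) and median-ratio centring (2388). It ranged from 525 to 3110 with 1 library left out, from 0 to 3946 over 9 ways of averaging libraries in pairs, and was 411 with the column-ending term, 4410 with array weights and the column-pair term, 106 in pair A only and 5642 in pair B only. Averaging within the column pairs, which the names do not tie to lines, left 0 genes in limma, and 0 changed at least 2-fold. At an unadjusted p under 0.05 there were 2652. The count of 636 genes changed at least 2-fold ranged from 258 to 822 with 1 library left out, and was 327 at a mean of at least 5 CPM, where fewer genes were tested, 211 with a pseudocount of 5 CPM, which shrinks folds, 239 with the column-ending term, 1195 with array weights and the column-pair term, 90 in pair A and 1777 in pair B, and from 0 to 871 averaged in pairs. Quantile normalization moved the share of rises among them from 15.4% to 28.7%, and at a mean of at least 5 CPM it was 19.9%.

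The 9 called lists became 0 with an estimated correlation, 14 with fry, 12 with the column-pair term and 20 in pair A only, and 9 to 12 with 1 library left out. The interaction count of 1972 ranged from 591 to 3956 with 1 library left out. For 101 named genes under 21 alternatives, 1771 of 2112 values kept direction and side of the threshold, 321 lost the call, 14 gained it and 6 reversed. Of the lost calls 75 were in pair A only, 49 with the column-ending term, 49 without control B1 and 45 without control B2. In pair A only, reversed values were MKI67 (0.98), CDC20 (1.24), FGF7 (-0.76), CSF1 (-0.22), the mitosis list (median 0.86) and the fibroblast markers (-0.27). In pair B only the replication list reversed (-0.40). With 1 library left out CDC20 ranged from -0.73 (without progerin A2) to 0.18 (without progerin B2), and was 0.11 without progerin B1. Where no reason is given, the cause was not tested.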

Other observations

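The gene families below were looked at after the data were seen, and the test of the contractile list was written down before its result was seen.

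Genes whose symbols begin with ADAMTS, mostly secreted proteases of the matrix, fell more often than other genes. Of 20 measured, 8 fell and 2 rose, with a median log2 fold change of -0.71, which was -0.52 after quantile normalization and -0.71 after median-ratio centring, and -0.80 and -0.77 in column pairs A and B. ADAMTS8 (-2.53 ± 0.31), ADAMTS7 (-2.01 ± 0.31), ADAMTS10 (-1.52 ± 0.22) and ADAMTS15 (-1.09 ± 0.17) fell, with negative fold changes in both pairs, while ADAMTS5 rose by 1.87 ± 0.35. In all, 20 groups of symbols were examined with a two-sided Fisher's exact test for rises and for falls, which made 40 tests, and the adjusted p for falls of ADAMTS genes was 0.00397 over the 40. Genes are not independent, and this group was picked out after its counts were seen. The other results under the threshold were fewer rises than among other genes for 450 ZNF genes (11, adjusted p = 0.000164) and fewer rises and falls for 156 RPL genes, pseudogenes included (1 and 2, adjusted p = 0.00209 and 0.000413). Falls among 17 KRT genes (5, adjusted p = 0.124) and the absence of falls among 52 PSM genes (adjusted p = 0.0679) did not pass, nor did any test of the HOX, TBX, FOX, PCDH, SLC, HLA, IGF, WNT, SEMA, CXCL, histone, NDUF, IL, CDK and KIF groups.

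FOXF1, a transcription factor gene next to FENDRR in the RefSeq annotation of GRCh38.p14, rose as well, by 1.76 ± 0.30 (adjusted p = 0.0110), with 1.83 in column pair A and 1.68 in pair B. FENDRR rose by 4.01 and 3.06 in the pairs. The strand setting of the counting is not given in the sources used here.

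A hypothesis was that the lower contractile genes follow how much each library expresses mitosis genes. With the mean level of the mitosis list as a covariate, the median log2 fold change of the contractile list was -0.58, against -0.53 without it, and 13 of 22 genes fell instead of 11. The same fit called 3971 genes, including all 2375 called without the covariate in the same direction. Mitosis levels of the progerin libraries lay on both sides of the controls (0.59 and 0.89 in pair A, -1.00 and -1.15 in pair B). The covariate could therefore hardly shift the group difference, and this fit alone cannot decide the question. The mean contractile level was -0.32 and -0.50 in progerin A libraries and -0.33 and -0.32 in progerin B libraries, against 0.27 to 0.53 in control libraries. In these libraries the lower contractile level thus did not follow the mitosis level. Other differences between lines or runs remain open.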
